A study of Arabidopsis thaliana with 2 samples.

How the data were processed

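Total RNA from whole seedlings of wild-type Columbia-0 and of OE-N6 was hybridised to 1 ATH1 array each, from 6 µg of total RNA labelled with biotin, per the labels' protocols. The deposited values are signal intensity on a linear scale, 1 value per probe set, and MAS5 is the tool named in the submitters' processing notes. Its version, scaling target and background settings are not given in the sources used here. The deposited intensity values have the same mean on both arrays (500) once the highest and lowest 2% of probe sets are left out, so each array carries 1 scaling factor. Detection calls were not used here. Such scaling sets the overall signal equal between arrays and would hide a change shared by most transcripts.

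Each array has 22810 probe sets, of which 64 are controls. The median signal of the other 22746 was 190 on both arrays. Probe sets were named from the platform annotation and matched by gene identifier to the RefSeq gene table of assembly TAIR10.1. No genome build is named for the array files, so coordinates are not printed, and that table was used only for names and neighbours. Of the non-control probe sets 13513 have 1 gene, 503 have several and 8730 are not listed and are unnamed here. Of those with 1 gene, 13436 matched the RefSeq table. Genes without a current symbol there are given by locus. Few genes with a symbol of their own are covered (1535 of 11060), so only 101 of the 654 loci in the lists had a probe set of their own. A further 7 list members were left out because their listed symbol did not match the table.

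Where a gene had several probe sets, the one with the highest mean signal was used, giving 13355 genes. Genes were kept when their mean signal was at or above the median of non-control probe sets (192), which left 5862. Signals under a floor, the 40th percentile of all values (111), were raised to it before the log2 ratio was taken. A gene under the floor on 1 array has only a bound, given as "at least". Genes were counted as higher or lower at 2-fold. No p-value or SD between replicates can be had with 1 array per genotype, and none is given. For gene lists with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size, drawn from genes in the same of 20 signal bins. A probe set with several genes counted as 1 member of a list when all its genes were in that list. A list was said to stand apart below the 2.5th or above the 97.5th percentile. A percentile describes these arrays and does not test the genotype.

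Genes were named by a rule fixed before the data were examined. It took the target, the 12 highest and 12 lowest log2 ratios among genes above the floor on both arrays, and up to 4 bounds in each direction. From each list standing apart it took up to 4 members in the direction of the median and the 1 furthest the other way, and from every other list up to 2 members. GID1C and PEX4 were named outside this rule, after their values were seen. The groups described under the other observations were chosen after the data were seen.

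The procedure was tested on simulated data made from the measured means of this comparison, with the spread of the log2 ratio at each signal level as noise. The spread was drawn from a normal distribution, so the simulation holds fewer extreme values than real arrays. Of 50 genes made 4-fold higher and 50 made 4-fold lower, all passed 2-fold among 5862 genes. Of 50 made 3-fold higher 48 did, and of 50 made 3-fold lower 50 did. Of 5654 genes left unchanged, 2 passed as higher and 0 as lower. A list of 8 genes shifted by 0.3 lay at the 99.96th percentile and an unshifted one at the 84.6th.

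The alternatives were median centring, quantile and loess scaling between the arrays, no filter, a filter at the 75th percentile, a floor at the 25th percentile, no floor, and the mean over a gene's probe sets. Counts were also made at 1.5-fold and 3-fold and with a pseudocount of 28.8, and lists with the mean, with 5 signal bins and without members shared between lists. Counting all probe sets, named or not, was added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9.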

Results

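Gene expression was measured in whole Arabidopsis thaliana seedlings of 2 genotypes, wild-type Columbia-0 and the transgenic line OE-N6, which was made to overexpress the locus AT4G16790. The labels call this gene NHRGP. Seedlings were 2 weeks old and had grown on diluted Murashige and Skoog medium with 2% sucrose at 22 °C, with 16 h of light and 8 h of dark per day. Each genotype was measured on 1 Affymetrix ATH1 array, a chip on which each transcript is read by a set of short probes. The comparison asks which transcripts differ between the overexpressing line and the wild type. With 1 array per genotype no difference has a replicate check, no test across replicates could be made, and the number of arrays limits the precision of every value. All ratios below are the OE-N6 signal over the wild-type signal, and "higher" and "lower" describe these arrays.

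The overexpressed gene itself had the highest ratio of all genes measured. AT4G16790 had a signal of 5171 on the OE-N6 array and 91.1 on the wild-type array. The wild-type signal lay under the floor of 111 signal units below which a value was raised to it, so the difference is given as at least 46.4-fold, a log2 ratio of at least 5.54. Without the floor the log2 ratio was 5.83. The neighbouring loci did not share this size of difference. AT4G16800 had a log2 ratio of 0.29, AT4G16770 one of 0.10, and the median of the 4 neighbouring loci that passed the signal filter was 0.06.

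Outside the target, most transcripts had similar signals on both arrays. Of 5862 genes that passed the filter, 95.2% lay within 1.5-fold, and 32 genes were at least 2-fold higher and 29 at least 2-fold lower in OE-N6. The log2 ratios had a median of -0.02 and an SD across genes of 0.31, which is a spread over genes and not an error. Over the 11373 probe sets that passed the filter, named or not, Pearson's r between the log2 signals of the arrays was 0.976; these are genes within arrays and not independent replicates. The same probe sets held 58 at least 2-fold higher and 55 at least 2-fold lower.

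**Figure D1:**
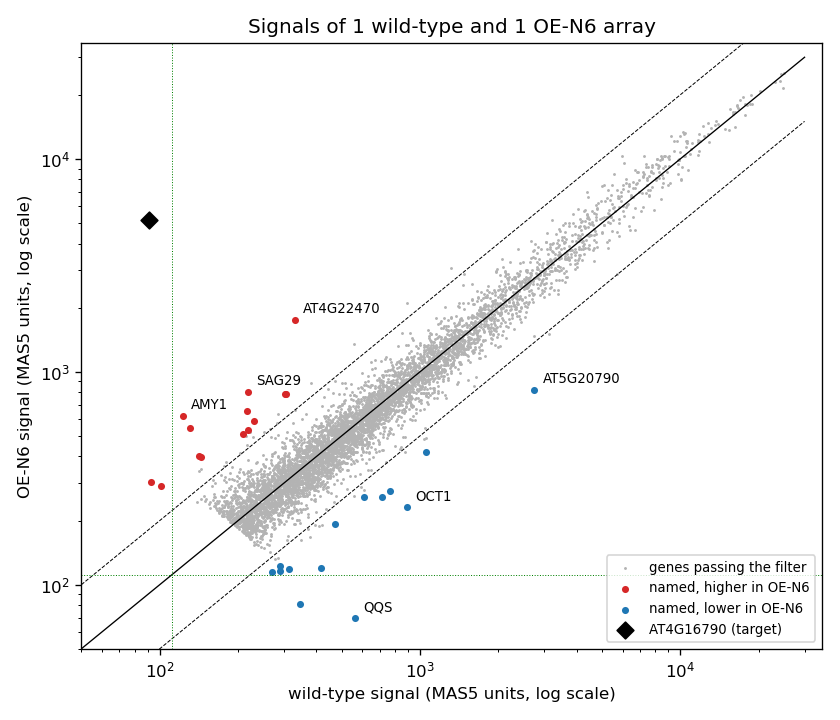
Signal of each gene on the wild-type array (x axis) and the OE-N6 array (y axis), both in MAS5 signal units on log scales, for the 5862 genes that passed the filter. The solid line marks equal signal, the dashed lines 2-fold differences and the dotted lines the floor of 111; AT4G16790, at 91.1 and 5171, stands far above the other genes.

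After the target, the highest ratios belonged to genes of several kinds. AT4G22470, of a lipid transfer protein family, had signals of 330 in the wild type and 1750 in OE-N6, a 5.30-fold difference. AMY1, an alpha-amylase that breaks down starch, was 5.05-fold higher, from 123 to 620. AT1G52060 and AT1G52070, which encode jacalin-type lectins, were 4.19-fold and 2.44-fold higher. SAG29, a sugar transporter of the SWEET family known from senescing tissue, was 3.69-fold higher, and AT4G04460, an aspartic protease, 3.02-fold higher. The expansin-like gene EXLA1 was 2.86-fold higher, GSTU25, a glutathione S-transferase, 2.61-fold higher, and AT1G30700, a berberine bridge enzyme-like oxidase, 2.56-fold higher. AT5G54370, AT5G62340 and AT3G46280 completed the 12 highest, at log2 ratios of 1.47, 1.36 and 1.28. For AT1G74010 and cwINV6, a member of the cell wall invertase family, the wild-type signal was under the floor, and OE-N6 was at least 2.73-fold and at least 2.61-fold higher.

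The lowest ratios were of similar size. QQS, an orphan gene known to affect starch content, had a signal of 562 in the wild type and 69.4 in OE-N6; the latter was under the floor, so the transcript was at least 5.05-fold lower. AT5G17340 was at least 3.11-fold lower, also with its OE-N6 signal under the floor. OCT1, an organic cation transporter, had signals of 887 and 231, which is 3.84-fold lower. AT1G08310 was 3.48-fold lower and AT5G20790 3.33-fold lower, the latter from 2745 to 823. AT5G19890, a class III peroxidase, was 2.38-fold lower. The other members of the 12 lowest were AT2G04460, AT3G20340, AT2G29300, AT1G19200, AT1G11410, AT1G09500, AT5G47690 and AT4G00500, with log2 ratios from -1.46 to -1.23.

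Gene families linked to loosening or remodelling of the cell wall had higher medians in OE-N6. List members are called measured here when they passed the signal filter. Expansins are proteins that loosen the wall, and their list also holds expansin-like genes such as EXLA1 and EXLB1. Of its 8 measured members, 5 were higher and 3 lower, with a median log2 ratio of 0.22. This median lay at the 98.9th percentile of 10000 random gene lists of the same size and matched signal. EXLA1 (1.52), EXPA18 (0.62), EXPA15 (0.33) and EXPA9 (0.27) had the highest log2 ratios, and EXLB1 the lowest at -0.83. Of 5 measured xyloglucan endotransglucosylase/hydrolases, which cut and rejoin wall xyloglucan, 4 were higher, with a median of 0.27 at the 98.2th percentile. EXGT-A3 (0.61), XTH16 (0.47), XTH18 (0.27) and XTH32 (0.16) lay above 0 and XTH19 (-0.39) below. Only EXLA1 among these 13 genes reached 2-fold. Without the signal filter the medians were 0.04 for the expansins and 0.02 for the xyloglucan enzymes, and neither list stood apart from random lists. Members under the floor on both arrays enter there with a log2 ratio of 0, which draws these medians toward 0. The expansin call also ended when EXPA18, which another list holds as well, was left out (median 0.17), and the xyloglucan enzyme call ended with the mean in place of the median (0.23).

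Of the other wall genes, COB, needed for oriented cellulose deposition, had a log2 ratio of 0.07, and GUT2, a xylan synthesis gene, 0.24. In the list of root-enriched genes the 3 measured members were all above 0, with EXPA18 at 0.62 and PYK10, an abundant root beta-glucosidase, at 0.05.

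Cold-response genes had a lower median in OE-N6. Of 6 measured members, 5 had log2 ratios below 0, and the median of -0.27 lay at the 0.34th percentile of matched random lists. AT4G33980 (-0.31), COR15B (-0.30) and COR27 (-0.24) were lower, LTI30 had nearly equal signals of 2399 and 2391, COR47 had 0.03, and a probe set shared by a pair of listed loci had the lowest value at -0.83. No member reached 2-fold.

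Nuclear photosynthesis genes had nearly equal signals on both arrays. The 5 measured genes of the photosystems and light-harvesting complexes had a median log2 ratio of -0.01, at the 19.8th percentile, with LHCB4.2 at -0.18 and PSAN at 0.16. Of the Calvin cycle genes, PRK had a log2 ratio of 0.04 and RCA 0.03. Of the 37 lists fixed before the data were examined, 4 had the 5 measured members needed for a percentile. Of those 4 lists, 3 lay outside the central 95% of random lists, where chance alone gives 0.2 if members vary independently. Members of a list may vary together, and chance would then put more lists outside.

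A further 21 lists had between 1 and 4 measured members, and only values are given. All 4 cytosolic ribosomal protein genes were above 0, with a median of 0.23, led by AT1G26880 at 0.37 and AT5G02870 at 0.27. Their median was 0.12 under quantile scaling and 0.16 under loess scaling. The defensin genes PDF1.2b and PDF1.2, which respond to jasmonate, had log2 ratios of -0.54 and -0.45. The clock gene GI had -0.54. Of the glucosinolate genes, BCAT4 had -0.36 and UGT74B1 -0.22. Among hormone genes, the gibberellin receptors GID1B, GID1A and GID1C had -0.26, -0.21 and 0.00, the ethylene signalling gene RTE1 -0.39, the auxin-responsive HAT2 -0.23 and WES1 -0.10, and the cytokinin-responsive RR16 0.00. The cell cycle genes PRL and AUR1 had 0.23 and 0.19. Values between -0.11 and 0.25 were found for the flavonoid genes UGT78D1 (-0.11) and UGT78D2 (0.04), STZ (0.17) of the touch and wound response, Fes1A (0.25) of the heat response and PYE (0.08) of the iron response. In the senescence list SAG29 was the high member and WRKY6 had -0.05, and in the detoxification list GSTU25 was the high member and NDB2 had -0.08. The other 12 lists gave no value. In 4 of them, among them the extensins and salicylic acid defence, the members with a probe set of their own did not pass the signal filter. In the other 8, among them the arabinogalactan proteins, abscisic acid response and phosphate starvation, no member had a probe set named here as its own, which says nothing about signal.

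Control measurements also differed between the arrays. Of the commonly used reference genes, GAPC2 had a log2 ratio of 0.04, PEX4 0.03 and AT4G34270 0.53. The RNA spikes added during labelling had a mean log2 ratio of 0.10 with an SD of 0.18 over 22 probe sets, and the hybridisation spikes 0.09 with an SD of 0.17 over 18. Where a gene had several probe sets, its 2 brightest differed in log2 ratio by a median of 0.19 over 41 genes, and by up to 0.73. Ratios of 3' to 5' or middle probe sets, a sign of RNA quality, were higher in OE-N6 for 9 of 10 pairs. All 10 come from actin, GAPDH and ubiquitin, and some share a 3' probe set, so they are not independent. For actin the 3' probe set was 1.61 times the 5' probe set in the wild type and 2.06 times in OE-N6, for an older actin pair 7.52 and 9.84 times, and for ubiquitin 1.16 and 1.27 times. The exception was a GAPDH pair, at 0.89 and 0.77. These ratios differ between the same arrays as every gene group above.

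**Figure D2:**
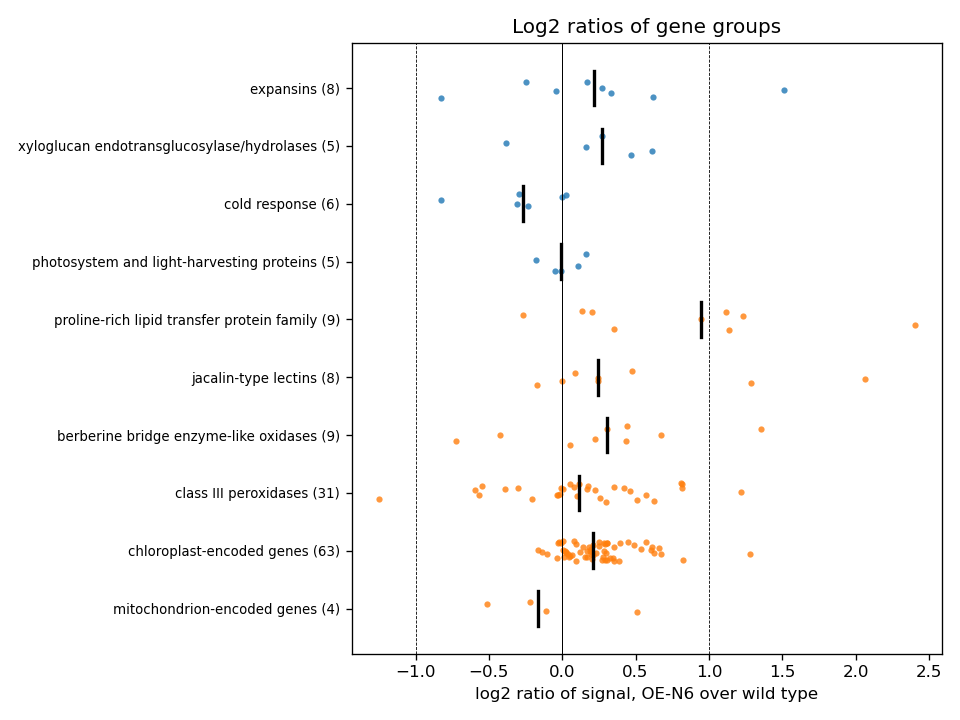
Log2 ratio of signal, OE-N6 over wild type (x axis), of the measured members of 10 gene groups, with the number of members in brackets and a black bar at each median. Blue groups were fixed before the data were examined and orange groups were chosen afterwards; the dashed lines mark 2-fold. The expansins and xyloglucan enzymes have medians of 0.22 and 0.27 and the cold-response genes one of -0.27.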

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

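The target gene kept a log2 ratio between 5.50 and 5.83 under the scaling, filter, floor and probe-set alternatives; the pseudocount was run for the counts only. All 28 named genes at 2-fold or more kept their direction and stayed past 2-fold under those of the same alternatives that gave them a value, and no other named gene reached it. The counts of genes at least 2-fold higher and lower stayed within 1.5 times of 32 and 29 under the scaling, floor, probe-set and pseudocount alternatives and without the filter. A filter at the 75th percentile left 2683 genes, of which 6 were higher and 6 lower. Calls at 2-fold were also more frequent among dim genes. Of 10 groups by mean signal, the dimmest held 2 higher and 7 lower, group 4 held 10 and 1, and the brightest 1 and 1. Lowering the threshold to 1.5-fold gave 143 higher and 141 lower, and raising it to 3-fold gave 6 and 5. Over all probe sets, a setting added after the data were seen, the counts were 58 and 55. Of the 3 lists standing apart, the cold-response list did so in every setting run for lists. Only 1 list stood apart without the filter, where the expansin median was 0.0439 and the xyloglucan enzyme median 0.0165. In that setting genes under the floor on both arrays enter with a log2 ratio of 0. Only 1 also stood apart at the 75th percentile filter, where the expansins and xyloglucan enzymes had too few members for a value. The mean of the xyloglucan enzymes was 0.23 and the median of expansins found in no other list 0.17, and neither stood apart; the cause was not tested. No paired analysis was possible because each genotype has 1 array. Low signals limit the data, since a gene under the floor on 1 array has only a bound.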

Other observations

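The groups in this part were chosen after the data were seen, except that the mitochondrion-encoded genes were listed before their own values were seen. The test of nuclear photosynthesis genes was also chosen after its result was seen, and its criterion was changed after that, as given with it. A scan covered 37 sets, 36 families of shared gene names and the chloroplast-encoded genes. Of these, 7 lay outside the central range of random lists, where chance gives 1.85 for independent sets. They are largely repeats: EXP, EXPA and XTH hold wall genes described above, and RPL and RPS overlap the chloroplast-encoded genes. Apart from these and the chloroplast set itself, only the LSM family remained, with a median of 0.20 over 6 members. The 7 are therefore not 7 separate results. Other scanned families overlap as well, so the chance figure for independent sets does not apply directly. Whether the separate results exceed chance was not settled. A further 7 groups were added by hand. The log2 ratios of neighbouring genes were not related across genes (r = 0.04 over 2652 pairs).

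Most transcripts encoded in the chloroplast genome were higher in OE-N6 in the deposited signals. Of 63 measured, 56 were higher and 7 lower, with a median log2 ratio of 0.21, above all 10000 matched random lists. The random lists were drawn gene by gene, while transcripts of 1 small genome may vary together. The 63 genes, and the classes below, are therefore not independent values, and the percentile overstates how far the group stands apart. The 14 ribosomal protein genes and 3 RNA polymerase genes of the chloroplast that passed the filter were all higher, with medians of 0.34 and 0.57, while the 5 photosystem I genes that passed had a median of 0.03. The gene ndhE, of the chloroplast NDH complex, was 2.43-fold higher, and rbcL, the large Rubisco subunit, had a log2 ratio of -0.16. On the same arrays the RNA spikes added during labelling had a mean log2 ratio of 0.10 and the hybridisation spikes 0.09. Of the ratios of 3' to 5' or middle control probe sets, 9 of 10 were also higher in OE-N6. The log2 difference was 0.35 for actin and 0.39 for an older actin pair. These ratios come from actin, GAPDH and ubiquitin alone and are not independent.

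A family of proline-rich lipid transfer proteins held several of the highest ratios. Of 9 measured members 8 were higher, with a median log2 ratio of 0.94 above all random lists. AT4G22470, AT4G12490 and AT4G12500 were 5.30-fold, 2.35-fold and 2.17-fold higher. Without these 3 the other 6 had a median of 0.28 at the 99.0th percentile. Of the 6, 2 were probe sets shared by several loci, at 1.14 (AT4G12510 and AT4G12520) and 0.94. The 4 with a probe set of their own ran from -0.27 to 0.35, too few for a percentile. The berberine bridge enzyme-like oxidases had a median of 0.30 over 9 members, and 0.26 at the 99.6th percentile without AT1G30700, which had prompted the list. The 9 include 2 shared probe sets, and AT4G20830 enters both by its own probe set (0.22) and by a shared one (0.05). The jacalin-type lectins had a median of 0.24 over 8 members, but without AT1G52060 and AT1G52070 the median of 0.16 lay at the 89.8th percentile, inside the central range. In these groups the members left out had high values and the random lists were not trimmed likewise, which lowers the percentiles of the rest. Shared probe sets stayed in, among them the one at 1.14, and the groups were chosen after the data were seen, which can raise them. The net bias of these percentiles is not known.

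The first pattern weighed is the higher level of chloroplast-encoded transcripts. A trend of the ratio with signal is argued against as its whole cause, since a loess correction that removes such a trend left a median of 0.17 above all random lists, with 46 of the 63 higher. A larger share of green tissue is not decided, because the criterion was set after its values were seen. The 8 nuclear photosynthesis genes had a median of 0.014 (SD across genes 0.10, a spread and not an error). Their median lay below the chloroplast median of 0.21 by more than that SD in all 4 scalings. Against chloroplast genes of matching brightness (median 0.16) this held in 3 of 4 scalings, and under quantile scaling the gap of 0.110 fell short of the SD of 0.113. This criterion is the third one used: by the first, the highest nuclear gene (0.16) lay below 0.21 and the explanation was excluded, and by the second that gene did not lie below the matching chloroplast genes and the explanation was left open. More labelling of RNA without poly(A) tails in OE-N6 stays open: the mitochondrion-encoded genes had a median of -0.17 with only 4 measured, 25S rRNA had a log2 ratio of 0.26, and 5S rRNA, under the floor on both arrays, had -0.58. Of 8 mitochondrion-encoded genes above the floor on 1 array or both without the filter, 7 were lower, some of them with an OE-N6 signal under the floor. A difference in RNA quality and an effect of the transgene were not tested apart from these and stay open, since genotype and array cannot be told apart with 1 array each.

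The second pattern is that some wall and root genes were higher in OE-N6, although 3 of 8 expansins were lower and the root-enriched list was too short for a percentile, for which a larger share of root in the sample is a possible explanation. The class III peroxidases, many of them expressed in roots, had a median of 0.11 over 31 members. Without the 5 seen first the median was 0.091 at the 96.4th percentile, with 16 of 26 higher, which falls between the values set in advance for and against that explanation. Those 5 were the extremes: AT3G01190 (1.22), AT2G18980 (0.82), AT5G66390 (0.81), AT5G64120 (0.81) and AT5G19890 (-1.25). The random lists kept their extremes, so leaving out mostly high members biases this median and its percentile downward. With single-gene probe sets alone the median of the rest was 0.08 over 23. A larger share of root therefore stays open, as does an effect of the genotype.

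The third pattern is that OCT1, AT1G08310 and AT5G20790, which background knowledge links to phosphate starvation, were among the lowest ratios. A lower phosphate-starvation response may account for it. Only 1 other such locus passed the filter, AT2G17280 at -0.41, and without the filter all 3 other loci with a probe set were lower. That is too few to decide.

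Among the 5229 probe sets that passed the filter and have no gene named here, 25 were at least 2-fold higher and 25 at least 2-fold lower. The highest ratio was 4.44-fold and the lowest at least 5.27-fold lower, with an OE-N6 signal under the floor.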
